A study of Mus musculus with 16 samples.

How the data were processed

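The series holds 16 mouse heart libraries made with droplet single-cell chemistry, in 5 experiments. There are 12 libraries of sorted cells and 4 libraries of nuclei. Per the labels, the sorted cells were gated on CD45, Ly6g, Ly6c and CD64, with CD11b added for the ZsGr and Arg1DTR sorts. The macHif1aKO experiment has 1 knockout and 1 control library from infarcted hearts at day 5 (MI, myocardial infarction). The ZsGr experiments follow cells carrying the Arg1 fate label ZsGr: 1 ZsGr+ and 1 ZsGr- library each at day 2 and day 30 of MI, and at day 5 after syngeneic heart transplant (HTX) in control and Hif1aKO settings. The Arg1DTR experiment has 1 library labelled DTR and 1 control library at day 3 of MI. The nuclei come from DRAQ5-sorted heart nuclei at day 3 of MI, with 2 resHif1aKO and 2 control libraries. The labels state 6 mice in each of these nuclei groups, but do not state whether replicates 1 and 2 came from separate animals.

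The authors made the deposited matrices with Cell Ranger, and the values are raw UMI counts per gene and cell barcode, with no normalization. Versions per the file headers were 3.1.0 for macHif1aKO, 7.1.0 for ZsGr and 8.0.0 for Arg1DTR and the nuclei. The submitters' notes name GRCm38 and mm10 as genome builds. Whether introns were counted, and any filter beyond cell calling, are not given in the sources used here. Sequences of ZsGr, the toxin receptor and the recombinases are not in the gene lists, so the transgenes could not be read, and gene-level Hif1a counts pool deleted and retained exons.

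Sorted cells were kept with at least 500 genes and at most 10% mitochondrial UMIs, and nuclei with at least 300 genes and at most 5%. Doublets were scored against 2 simulated doublets per cell, and 0.8% of passing barcodes per 1000 deposited barcodes were removed, which was 0.822 to 10.0% of a library. Genes seen in at least 10 cells were used. Within each experiment, 2000 variable genes, 30 principal components and 20 neighbours went into Leiden clustering at resolution 1. Arg1, Hif1a, the glycolysis and hypoxia lists, sex-linked genes and immediate early genes were left out of the genes clustered on, so that no class was built on the outcome. Clusters were named from marker lists written before the data were examined. The naming thresholds, the rule against contrary markers and the rule for other lineages were set after the clusters had been seen. A class name ends in "like" because it rests on transcripts alone, and clusters failing the rules stay unnamed.

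Kept cells and median UMIs per cell were: macHif1a control 2969 and 8346, macHif1aKO 4943 and 9386; ZsGr+ day 2 2355 and 13470, ZsGr- day 2 5336 and 2801; ZsGr+ day 30 845 and 8653, ZsGr- day 30 2160 and 7695. In HTX they were ZsGr+ control 6530 and 5233, ZsGr- control 5738 and 1889.5, ZsGr+ Hif1aKO 2393 and 16923, ZsGr- Hif1aKO 2214 and 7070. The Arg1DTR experiment kept 4559 control cells at 5452 and 3011 DTR cells at 17457. Nuclei numbered 9731 at 5609 and 8613 at 6843 for resHif1aKO, and 10827 at 3606 and 10982 at 4280.5 for controls. Summed UMIs of sorted cells ranged from 8794761 in ZsGr+ day 30 to 89565188 in ZsGr+ control HTX. Where a gene had no UMI, a floor of 3 counts per library was used, which in ZsGr+ day 30 is 0.341 CPM (UMIs of a gene scaled to 1e6 UMIs in the library).

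The 10 comparisons of sorted cells with 1 library per group carry no test. Values there are CPM over all kept cells, folds with 95% intervals from exact counting statistics, and list medians of log2 (CPM + 1) ratios set against 10000 random lists of matched expression. A list's percentile is its place among those random lists. Genes were named by a rule fixed before the data were examined: at least 100 UMIs over both libraries and 50 CPM in either, then the 10 highest and 10 lowest log2 ratios, leaving out mitochondrial, ribosomal, predicted, immunoglobulin, T cell receptor, hemoglobin and sex-linked genes. The intervals hold counting error only and no spread between animals.

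Replicated tests used edgeR quasi-likelihood fits with TMM scaling on UMI counts summed per library, Benjamini-Hochberg adjustment and a threshold of 0.05. For ZsGr, the 4 pairs of ZsGr+ and ZsGr- libraries were fitted with the experiment as a block, and the 12 highest and 12 lowest called genes with the same sign in 4 pairs and a mean log2 CPM of at least 4 were named. For nuclei, 5 classes with at least 50 nuclei in every library were tested without a block, and the 8 highest and 8 lowest called genes were named where both libraries of each group lay beyond both of the other. Class shares in nuclei were tested with the same kind of fit on nuclei counts. The 25 gene lists, fixed before the data were examined, were tested with limma camera at a preset correlation of 0.01 and again with an estimated correlation. Cells carrying an Arg1 UMI were also counted after each cell had been thinned to 2000 UMIs.

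Alternatives tried were DESeq2, RLE size factors, no filter on low counts, a replicate block, leaving out each library or pair, doublets kept, at least 1000 genes per cell (500 per nucleus), no mitochondrial filter, TMM scaling of single libraries, resolutions 0.5 and 1.5, and only clusters named monocyte or macrophage. Leaving out clusters of other lineages, and leaving unnamed clusters out of the total, were chosen after the data had been seen. The fits were tested on simulated data with 200 changed genes: 58% of 2-fold and 88% of 4-fold changes were recovered over the ZsGr pairs with 10.7% false calls, and 69 to 85% and 90 to 98% in the nuclei classes with 3.86 to 10.7% false calls. A doubled oxidative phosphorylation list was recovered at a median of 0.98 and percentile 100, while 1 of 24 other lists lay beyond the central 95%. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.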

Results

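Every sorted-cell group in these comparisons is 1 library (n = 1 and 1), so the 95% intervals give counting error alone, and differences between animals, sorts and runs cannot be separated from the groups. Median depth, the sex-linked transcripts Xist and Ddx3y and the processing batch also differed between libraries: in macHif1aKO against control, Xist was 284.7 against 100.4 CPM and Ddx3y 3.43 against 19.3 CPM. Control HTX libraries had 0.0558 and 0.0542 CPM of Xist, and the Hif1aKO HTX libraries 149 and 102 CPM, while Ddx3y was 52.7 and 82.7 CPM in control and 62.6 and 60.8 CPM in Hif1aKO HTX libraries, so female cells went with genotype and male cells were in both. Both day 30 libraries of MI had no Ddx3y UMI, against 1036 and 456 UMIs at day 2, so sex differed with time. Within the day 2 pair, Xist was 88.4 CPM in ZsGr+ and 299 CPM in ZsGr- cells, and Ddx3y 23.3 and 14.7 CPM. The mix of sexes therefore also differed with the label there. Sums over all kept cells mix expression per cell with the kinds of cells sorted.

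The first comparison asked how loss of Hif1a in macrophages changed cells of the infarcted heart at day 5. Hif1a itself was 62.5 CPM in macHif1aKO and 61.3 CPM in control (1.02-fold, 95% interval 0.965 to 1.08), and pooled exons cannot show the floxed deletion. Spp1, which encodes the matrix protein osteopontin made by wound macrophages, was 6.45-fold higher (6.41 to 6.49; 21490 against 3332 CPM). The next genes by fold included the protease gene Ctsk at 5.82-fold (5.46 to 6.21), Atp6v0d2 at 4.05-fold (3.79 to 4.34) and Acp5 at 3.18-fold (3.07 to 3.29). The neutrophil attractant Cxcl1 was 3.30-fold higher (3.13 to 3.48), and Pdpn, Ccl9, Cd9 and S100a4 rose 2.47-fold to 3.22-fold. Arg1, the arginase of repair macrophages that gives the fate label its name, was 3.07-fold higher (2.86 to 3.29; 92.1 against 30.0 CPM). The 10 genes with the largest falls were mostly matrix and vessel genes, led by Igfbp7 (9.35-fold lower, 9.05 to 9.66), Ptn (8.25-fold lower) and Postn (5.18-fold lower).

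Gene programs moved with these genes in macHif1aKO. Lipid-associated macrophage genes had a median log2 ratio of 0.55 (13 of 15 higher, percentile 100), glycolysis 0.26 (10 of 15 higher, percentile 99.96) and oxidative phosphorylation 0.20 (14 of 16 higher). Hypoxia-inducible targets, the genes that Hif1a drives, had a median of -0.27 (4 of 18 higher, percentile 4.90, inside the central 95%). Antigen presentation by MHC class II fell by 0.83 on the log2 scale (0 of 8 higher) and resident macrophage genes fell by 0.54 (2 of 10 higher). Fibroblast, endothelial and cardiomyocyte markers fell by 1.45, 1.79 and 1.60, and matrix genes fell by 1.61. In clusters named monocyte or macrophage alone, the glycolysis median was -0.033 and the matrix median 0.19. That setting left out an unnamed cluster of 844 cells with Hilpda and Spp1 among its top genes, whose closest class was lipid-associated macrophage. TMM scaling moved all log2 ratios of this comparison by 0.22.

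Arg1 UMIs were found in 18.5% of macHif1aKO cells (17.4 to 19.6) and 7.71% of control cells (6.78 to 8.73), at median depths of 9386 and 8346 UMIs. Thinned to 2000 UMIs the shares were 6.60% and 2.29%, with 544 and 275 shallow cells left out. T or NK-like cells, which should lack Arg1, showed 5.28% at a median of 4181 UMIs and 2.08% at 4286 UMIs (1.97% and 0.589% thinned), and neutrophil-like cells 3.71% and 0.437% at 2823 and 2890 UMIs. Unnamed clusters held 23.5% of macHif1aKO and 12.97% of control cells, and MHC-II macrophage-like cells were 11.4% and 17.9%.

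At day 2 of MI, ZsGr+ cells were compared with ZsGr- cells to describe what cells with a history of Arg1 expression carry. Arg1 was 2.89-fold higher in ZsGr+ cells (2.82 to 2.96; 707 against 245 CPM), and Hif1a was lower (139 against 256 CPM, 0.543-fold). The largest rises included Npl 4.47-fold (4.09 to 4.89), Cbr2 3.61-fold, Pf4 3.51-fold, the folate receptor Folr2 3.22-fold, Ccl8 2.96-fold and the apoptotic-cell bridge Gas6 2.94-fold. The inflammatory monocyte genes Ly6c2, Plac8 and Vcan were 25.9-fold (23.0 to 29.2), 19.1-fold and 14.95-fold lower, and the MHC class II genes H2-Eb1, H2-Aa and H2-Ab1 were 24.4-fold, 22.3-fold and 16.8-fold lower. List medians were 1.05 for resident macrophage genes (9 of 10 higher), 0.91 for cell cycle (14 of 14), 0.66 for lipid-associated genes (14 of 15), 0.36 for hypoxia-inducible targets (14 of 19), -0.21 for efferocytosis and scavenging (4 of 10, percentile 14.93, inside the central 95%), -3.20 for MHC class II (0 of 8), -2.80 for monocyte genes (0 of 10) and -1.04 for interferon response (0 of 15). Within clusters named monocyte or macrophage, the hypoxia median was -0.16. That setting kept 446 of 2355 ZsGr+ cells. It left out an unnamed cluster of 970 cells over the MI libraries with Hilpda, Arg1 and Spp1 among its top genes, whose closest class was lipid-associated macrophage.

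An Arg1 UMI was present in 75.5% of ZsGr+ and 25.5% of ZsGr- cells at day 2 (medians 13470 and 2801 UMIs), and in 50.3% and 18.8% after thinning, with 311 and 2122 cells left out. Neutrophil-like ZsGr- cells gave 12.2% (of 41 cells, median 2510 UMIs). Monocyte-like cells made up 0.934% of ZsGr+ and 22.5% of ZsGr- cells, while 66.9% and 63.9% of cells stayed unnamed.

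By day 30 of MI the difference in Arg1 ran the other way: Arg1 was 4.89 CPM in ZsGr+ and 23.4 CPM in ZsGr- cells, 4.78-fold lower (3.49 to 6.70), and Hif1a was 59.4 against 131.5 CPM. ZsGr+ cells instead carried genes of long-lived tissue macrophages. The hemoglobin scavenger receptor Cd163 was 21.0-fold higher (18.5 to 23.9), Lyve1 6.76-fold (6.15 to 7.45), the phosphatidylserine receptor Timd4 6.47-fold (5.40 to 7.79), Cbr2 5.49-fold, Folr2 5.25-fold and the complement receptor Vsig4 4.74-fold. Monocyte-derived and dendritic genes were scarce: Plac8 was 150-fold lower (103 to 228), Cd209a 134-fold lower (64.9 to 334), and Hp and Chil3 had no UMI, at least 350-fold and 216-fold lower against a floor of 3 counts per library. All 13 resident macrophage genes and all 12 complement genes measured were higher (medians 1.83 and 0.83). Glycolysis fell by 0.41 (0 of 15 higher), hypoxia-inducible targets by 0.36 (4 of 17 higher) and monocyte genes by 2.91. Within clusters named monocyte or macrophage, the hypoxia median was 0.0047. Other markers moved too: endothelial markers fell by 1.54 (0 of 8 higher), angiogenesis by 1.21 (0 of 11) and neutrophil markers by 1.29 (1 of 6), and cardiomyocyte markers rose by 0.72 (7 of 7). Endothelial-like cells were 3.43% of ZsGr+ and 13.2% of ZsGr- cells. A resident macrophage-like cluster held 30.4% of ZsGr+ and 6.30% of ZsGr- cells. Monocyte-like cells were 0.118% and 14.4%, and 16.2% and 13.8% stayed unnamed. Arg1 UMIs were seen in 2.96% and 4.40% of cells, or 1.33% and 1.97% thinned with 100 and 221 cells left out. In the same libraries endothelial-like cells gave 0% of 29 ZsGr+ cells (upper bound 11.9%) and 0% of 285 ZsGr- cells (upper bound 1.29%), at medians of 5806 and 4821 UMIs, and fibroblast-like ZsGr- cells 0% of 124 (upper bound 2.93%, median 9527.5 UMIs). The ZsGr- share of all cells lay above these bounds before thinning but not clearly after it (1.39 to 2.68% against an endothelial upper bound of 1.60%), and the ZsGr+ share did not.

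From day 2 to day 30, ZsGr+ cells lost Arg1 (145-fold lower, 107 to 200), Spp1 (84.8-fold, 81.0 to 88.9), the fatty acid carrier Fabp5 (66.3-fold) and Gpnmb (26.4-fold), and gained the MHC class II genes H2-Eb1 (280-fold higher, 259.8 to 302), H2-Aa (205-fold) and H2-Ab1 (142-fold). ZsGr- cells lost the monocyte attractants Ccl7 (27.5-fold lower) and Ccl2 (13.4-fold), Hmox1 (11.4-fold), Spp1 (10.9-fold) and Arg1 (10.5-fold, 9.51 to 11.5). Cd207, a gene known from Langerhans and dendritic cells, appeared in ZsGr- cells at 97.2 CPM from 0 UMIs, at least 1007-fold higher. In these libraries it was among the top genes of the MHC-II macrophage-like cluster. That cluster held 34.4% of ZsGr+ and 28.9% of ZsGr- cells at day 30, so the rise does not show dendritic cells particular to ZsGr- cells. MHC class II medians were 6.22 in ZsGr+ and 2.85 in ZsGr- cells, and lipid-associated medians -1.78 and -1.36. Glycolysis medians were -1.62 and -0.92. The rises of Jchain, Dcn, Comp and Clec3b at day 30 come with matrix list medians of 2.99 and 2.25 and an endothelial median of 4.35 in ZsGr- cells, genes of fibroblasts, plasma cells and vessels. With clusters of other lineages left out, the matrix medians were -0.96 in ZsGr+ and -0.50 in ZsGr- cells. TMM scaling moved log2 ratios by -0.47 in ZsGr+, -0.16 in ZsGr- cells and 0.18 in the day 2 comparison of label states.

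**Figure D1:**
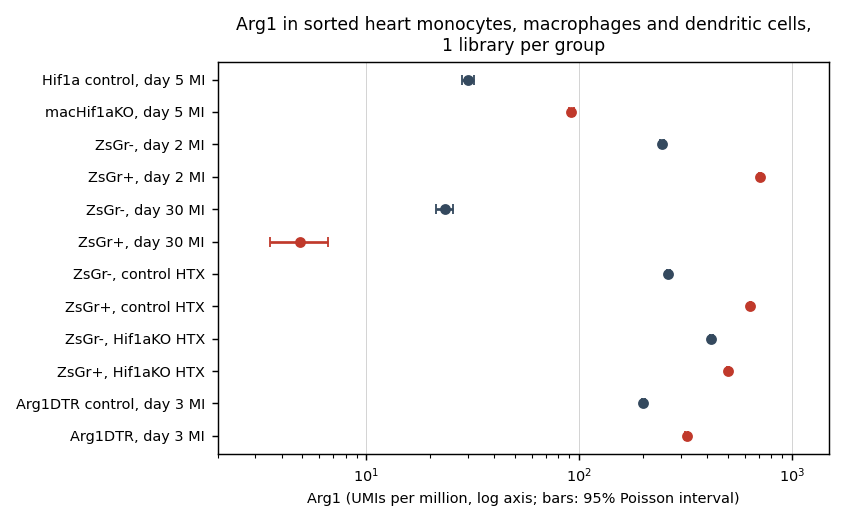
Arg1 in CPM (log axis) in each of the 12 sorted libraries, with 95% Poisson intervals as bars. Values span 4.89 CPM in ZsGr+ cells at day 30 to 707 CPM in ZsGr+ cells at day 2.

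In control transplants at day 5, ZsGr+ cells again had more Arg1 than ZsGr- cells (638 against 263 CPM, 2.43-fold, 2.38 to 2.48) and less Hif1a (134 against 176 CPM). The growth factor Igf1 was 7.15-fold higher (6.71 to 7.62), the iron exporter Slc40a1 6.23-fold, Fabp5 5.03-fold, Gdf15 4.93-fold, Gas6 4.82-fold, Spp1 4.36-fold and Apoe 3.95-fold. Ly6c2 was 194-fold lower (154 to 247), Plac8 102-fold lower, and the neutrophil and monocyte genes S100a9 and S100a8 were 27.0-fold and 23.7-fold lower. Medians were 1.32 for resident macrophage genes (11 of 11 higher), 1.30 for lipid-associated genes (12 of 15), 0.48 for glycolysis (10 of 15), -2.82 for monocyte genes and -2.38 for MHC class II. Neutrophil-like cells were 1.32% of ZsGr+ and 16.6% of ZsGr- cells, monocyte-like cells 0.674% and 10.8%, and MHC-II macrophage-like cells 13.23% and 6.19%, with 54.5% and 60.2% unnamed. The MHC-II macrophage-like difference turned from 7.04 to -1.71 percentage points at resolution 1.5. Arg1 UMIs were in 58.2% and 20.04% of cells (40.4% and 13.8% thinned, 2513 and 2893 left out), against 22.1% and 3.88% of neutrophil-like cells at medians of 3925 and 4619 UMIs.

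In Hif1aKO transplants, Hif1a was 194 CPM in ZsGr+ and 176 CPM in ZsGr- cells (1.10-fold), and the gap in Arg1 between label states was 1.197-fold (1.17 to 1.22; 501 against 419 CPM). Within clusters named monocyte or macrophage the log2 ratio of Arg1 turned to -0.27, but that setting left out an unnamed cluster of 1177 cells with Spp1 and Arg1 among its top genes. Macrophage genes still marked the ZsGr+ cells, with Slc40a1 6.52-fold, Igf1 4.58-fold and the efferocytosis receptor Mertk 4.11-fold higher (3.94 to 4.29), and the acute-phase gene Saa3 6.55-fold higher. Ly6c2 and Plac8 were 290-fold (210.1 to 412) and 138-fold lower. Resident macrophage genes had a median of 1.40 (10 of 10 higher), complement genes 0.71, lipid-associated genes 0.73, MHC class II -1.95 and monocyte genes -2.39. Glycolysis fell by 0.17 (1 of 15 higher, percentile 13.77, inside the central 95%) and oxidative phosphorylation by 0.31 (1 of 16 higher, percentile 0.36). Erythroid markers had a median of 4.01. Neutrophil-like cells were 1.25% of ZsGr+ and 16.1% of ZsGr- cells, monocyte-like cells 0.334% and 29.4%, and 45.0% and 30.8% stayed unnamed. MHC-II macrophage-like cells were 24.5% of ZsGr+ and 11.2% of ZsGr- cells, a difference that turned from 13.4 to -2.95 percentage points at resolution 1.5. Arg1 UMIs were in 57.7% and 33.2% of cells, and in 33.2% and 23.3% after thinning with 304 and 288 left out. Neutrophil-like cells gave 2.80% in the ZsGr- library at a median of 4156 UMIs.

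**Figure D2:**
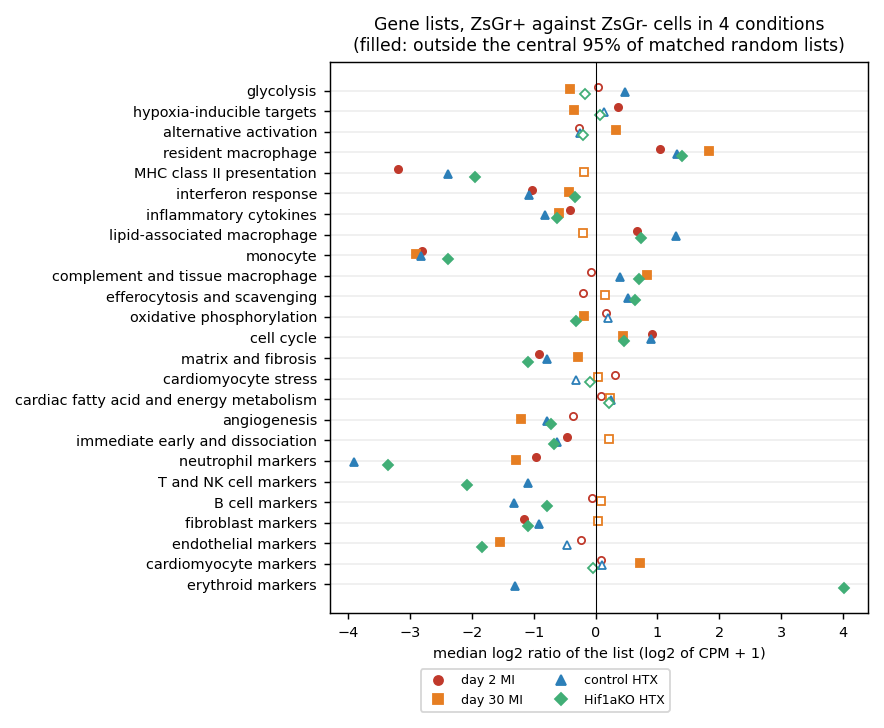
Median log2 ratio of each gene list, ZsGr+ over ZsGr-, in 4 conditions with 1 library per group; filled points lie outside the central 95% of matched random lists. Resident macrophage medians are 1.05, 1.83, 1.32 and 1.40, and monocyte medians -2.80, -2.91, -2.82 and -2.39.

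Hif1aKO and control transplants were then compared within each label state. In ZsGr+ cells Hif1a was 1.45-fold higher in the knockout setting (1.42 to 1.49; pooled exons) and Arg1 was lower (0.785-fold, 0.774 to 0.796). The hypoxia-induced lipid droplet gene Hilpda was 2.03-fold lower (1.98 to 2.09), the protease Mmp9 2.24-fold lower, the chemokine genes Cxcl3 and Ppbp 3.84-fold and 3.63-fold lower, and Ccl4 1.87-fold lower. Saa3 was 70.7-fold higher (65.1 to 76.9), and Camk1d and Cmss1 rose 3.52-fold and 2.97-fold. Glycolysis fell by 0.38 (2 of 15 higher, percentile 0.09), oxidative phosphorylation by 0.35 (1 of 16) and inflammatory cytokines by 0.50 (1 of 14), while interferon response rose by 0.46 (14 of 16). Markers of other cells moved too, with medians of -0.78 for endothelium and 2.69 for erythroid cells, and both changed direction when other cells were counted. Hypoxia-inducible targets as a list did not fall, at a median of 0.065 (10 of 19 higher, percentile 15.78), and lipid-associated genes had a median of -0.088 (6 of 15). TMM scaling moved log2 ratios by -0.26 here and by 0.31 in the control transplants.

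In ZsGr- cells Hif1a did not differ (1.00-fold, 0.966 to 1.04), and Arg1 was 1.59-fold higher in Hif1aKO transplants (1.55 to 1.64). Ctla2a was 7.16-fold higher (6.35 to 8.08), the granzyme gene Gzma 4.85-fold, Saa3 3.04-fold and Gpnmb 2.18-fold. S100a8 and S100a9 were 2.34-fold and 2.32-fold lower, the MHC class II regulator Ciita 2.36-fold lower, Cxcl9 2.27-fold lower and Jchain 12.6-fold lower. Lipid-associated genes had a median of 0.53 (15 of 15 higher), glycolysis 0.19 (12 of 15), hypoxia-inducible targets 0.23 (16 of 19) and MHC class II -0.79 (0 of 8). Markers of other cells moved with them, T and NK cells by 0.54 (7 of 7 higher), fibroblasts by 0.48 (9 of 9), endothelium by 0.49 (6 of 8) and neutrophils by -0.71 (1 of 9). Monocyte-like cells were 29.4% of the Hif1aKO and 10.8% of the control ZsGr- cells, with 30.8% and 60.2% unnamed, at median depths of 7070 and 1889.5 UMIs.

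Taken over the 4 pairs (n = 4 ZsGr+ and 4 ZsGr- libraries, edgeR with a block for the pair), 1721 of 17229 genes differed, 626 higher and 1095 lower in ZsGr+ cells. The hemoglobin and iron handling genes Cd163 (log2 2.69 ± 0.45, SE; adjusted p = 0.00787) and Slc40a1 (2.38 ± 0.23; adjusted p = 0.000852), the hyaluronan receptor Lyve1 (2.58 ± 0.27; adjusted p = 0.00115) and Npl (2.23 ± 0.16; adjusted p = 0.000169) led the genes higher in 4 of 4 pairs. Pdgfc, Igf1, Gas6, Ccl8, Cbr2, Folr2, Cela1 and Ctla2b followed at log2 1.74 to 2.10. Lyve1 was well expressed only at day 30 (197 CPM in ZsGr+ against 29.1 CPM in ZsGr- cells). In the other pairs it was near the floor, at 2.56 against 0.451 CPM at day 2 and 1.57 against 0.19 CPM in control HTX. In Hif1aKO HTX it was 0.446 against 0.249 CPM. Plac8 (-6.24 ± 0.57; adjusted p = 0.000603), Cd209a (-5.50 ± 0.56), Ly6c2 (-5.43 ± 1.15; adjusted p = 0.0209) and Ifitm6 (-3.42 ± 0.13; adjusted p = 1.55e-05) were lower in 4 of 4 pairs, as were Chil3, S100a8 and S100a9 (-3.72 to -3.08). Arg1 itself was not called (log2 0.45, adjusted p = 0.67), nor was Hif1a (-0.51, adjusted p = 0.18). Leaving out the control or the Hif1aKO transplant pair left 535 or 646 genes.

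Of the 14 resident macrophage genes, 10 were higher over the 4 pairs, and 13 adjusted over the list alone (camera adjusted p = 1.15e-12; adjusted p = 0.12 with an estimated correlation). Monocyte genes were lower in 9 of 10 and 9 adjusted over the list alone (1.32e-11; adjusted p = 0.12 with an estimated correlation). All 8 MHC class II genes were lower, also 8 adjusted over the list alone (1.07e-07; adjusted p = 0.167 with an estimated correlation). Cell cycle genes were higher in 12 of 14, 13 adjusted over the list alone (6.29e-10; adjusted p = 0.167 with an estimated correlation), and interferon genes lower in 7 of 16, 11 adjusted over the list alone (2.51e-07; adjusted p = 0.243 with an estimated correlation). Lipid-associated genes were higher in 3 of 15, 6 adjusted over the list alone (0.00335; adjusted p = 0.424 with an estimated correlation). Glycolysis had 0 of 16 called by edgeR, 0 by DESeq2 and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05 in edgeR and 3 in DESeq2 (camera adjusted p = 0.546), and hypoxia-inducible targets 1 of 19 (0.225). In all 17 of 25 lists were called by camera, 5 up and 12 down, and 0 with an estimated correlation.

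Markers of other cells were also lower in ZsGr+ libraries over the 4 pairs. Neutrophil markers had a median of -3.08 (7 of 9 called, 8 adjusted over the list alone; camera adjusted p = 1.11e-07; adjusted p = 0.167 with an estimated correlation) and T and NK markers -2.41 (7 of 9, 9 adjusted over the list alone; 8.96e-08; adjusted p = 0.167 with an estimated correlation). Endothelial markers had a median of -1.23 (4 of 8, 6 adjusted over the list alone; 3.62e-05; adjusted p = 0.24 with an estimated correlation) and fibroblast markers -0.82 (4 of 9, 8 adjusted over the list alone; 0.000137; adjusted p = 0.167 with an estimated correlation). With clusters of other lineages left out, a setting chosen after the data had been seen, 14 of 25 lists were called, and none with an estimated correlation (lowest adjusted p = 0.174). The lipid-associated list then had 1 of 15 genes called and lost its call (camera adjusted p = 0.0557), and cell cycle had 4 of 14 called (1.01e-08; adjusted p = 0.201 with an estimated correlation).

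The Arg1DTR experiment compared, at day 3 of MI, a library from mice built for ablation of Arg1-lineage cells with its control. Whether toxin was given is not stated in the sources used here. Arg1 was 1.60-fold higher in the DTR library (1.56 to 1.63; 320 against 200 CPM) and Hif1a 1.63-fold higher (180 against 110 CPM). Neutrophil granule and alarm genes rose most: Ngp 169-fold (112 to 270), S100a9 7.96-fold (7.62 to 8.31), S100a8 7.47-fold, and with them Cxcl3 5.48-fold, Areg 3.07-fold and the cytokine gene Il1b 2.73-fold (2.68 to 2.78). The largest falls included Mfge8, a bridge to apoptotic cells, at 3.68-fold lower (3.46 to 3.92), Pdgfc 3.71-fold, Fcrls 2.95-fold and Apoe 2.59-fold lower (2.58 to 2.61). Efferocytosis and scavenging genes fell by 0.30 (2 of 12 higher, percentile 0.41). Neutrophil and B cell markers had medians of 1.40 (7 of 9 higher) and 1.18 (5 of 5). All 14 inflammatory cytokine genes were higher (median 0.70), monocyte genes had a median of 0.36 (8 of 10), resident macrophage genes fell by 0.71 (3 of 12 higher), complement genes by 0.70 (2 of 12), lipid-associated genes by 0.55 (1 of 15) and interferon response by 0.68 (0 of 16).

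Monocyte-like cells were 16.3% of DTR and 3.66% of control cells, neutrophil-like cells 1.196% and 0.505%, B-like cells 2.86% and 0.197%, and resident macrophage-like cells 1.66% and 8.34%, with 59.9% and 68.4% unnamed. Arg1 UMIs were in 45.3% and 37.8% of cells at medians of 17457 and 5452 UMIs, and in 23.3% and 17.95% after thinning with 463 and 1530 left out; neutrophil-like cells gave 13.9% and 17.4% at 4766.5 and 5311 UMIs, in 36 and 23 cells.

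**Figure D3:**
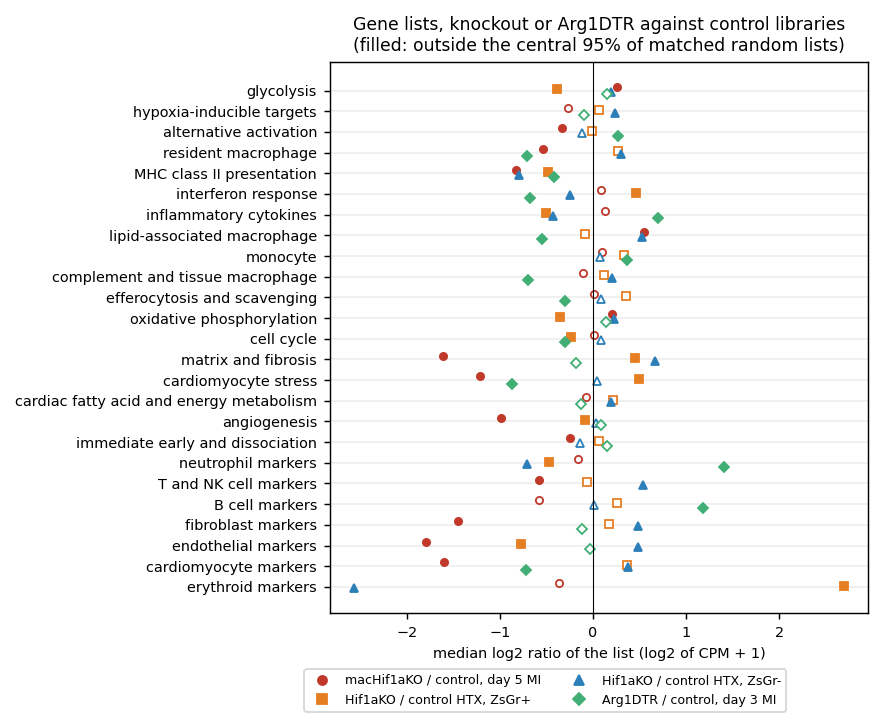
Median log2 ratio of each gene list in 4 comparisons of knockout or Arg1DTR with control libraries, 1 library per group; filled points lie outside the central 95% of matched random lists. Lipid-associated medians are 0.55 in macHif1aKO, 0.53 in ZsGr- HTX cells, -0.088 in ZsGr+ HTX cells and -0.55 in Arg1DTR.

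The nuclei compared hearts lacking Hif1a in resident macrophages with controls at day 3 of MI (n = 2 and 2 libraries). If the replicates share animals, which the labels do not settle, the p-values measure technical spread alone, and Xist (725 and 751 against 415 and 416 CPM) and depth per nucleus differed with genotype. Replicates of a group lay close together, with Ddx3y at 25.1 and 25.5 CPM in resHif1aKO and 38.9 and 39.3 CPM in control. Their spread beyond counting error, as fitted by edgeR, was 2.82 to 8.18% of the mean in the 5 classes. Spread between animals can therefore not be assumed to be in these tests. Hif1a was not called lower in any of the 5 classes tested: in macrophage or monocyte nuclei it was 186 and 186 against 161 and 162 CPM (log2 0.17 ± 0.04, adjusted p = 0.0173), and in cardiomyocyte, fibroblast, endothelial and pericyte nuclei its log2 fold was -0.081 to 0.052 without a call. Pooled exons include those kept after deletion, and resident cells are a part of this class. Arg1 was not called in any of the 5 classes (macrophage or monocyte log2 0.075 ± 0.067, adjusted p = 0.716).

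Macrophage or monocyte nuclei had 322 genes past the threshold, 192 higher and 130 lower, and 1932 at an unadjusted p under 0.05. Genes at low CPM led the rise: Erc2 (log2 2.52 ± 0.33, adjusted p = 3.28e-05; 9.62 and 4.12 against 0.848 and 1.46 CPM), Bcl11b (2.38 ± 0.52), Jchain (1.71 ± 0.37), the sugar-sensing factor Mlxipl (1.57 ± 0.28) and the interferon gene Ifi208 (1.34 ± 0.30). Bcl11b is also among the top genes of a T or NK-like cluster, and Jchain is a plasma cell gene. T or NK-like nuclei were 1.99% and 2.19% in resHif1aKO against 1.25% and 1.52% in control, a difference not called. Whether RNA or nuclei of lymphocytes account for these rises was not tested. The largest falls were airway secretory genes that heart cells do not normally make: Scgb1a1 (-4.41 ± 0.41, adjusted p = 1.01e-07; 0.122 and 0.253 against 3.39 and 4.62 CPM), Scgb3a1 on 3 against 118 UMIs (39.1-fold lower, 13.04 to 192), and Bpifa1 and Reg3g with no UMI in the knockout (at least 21.8-fold and 10.9-fold lower against a floor of 3 counts over the group). Glycolysis (median 0.020, camera adjusted p = 0.347) and hypoxia-inducible targets (0.038, 0.698) were not called. Cardiomyocyte markers rose in macrophage nuclei (median 0.22, 4 of 9 called, 8 adjusted over the list alone; 2.2e-12; adjusted p = 0.721 with an estimated correlation), as did matrix genes (0.14, 3 of 17, 10 adjusted over the list alone; 3.54e-07; adjusted p = 0.721 with an estimated correlation). The cardiomyocyte list also rose in endothelial (0.32) and pericyte nuclei (0.17) and fell in fibroblast nuclei (-0.080). A shallow cluster of the macrophage class, with a median of 1075.5 UMIs, had Nppa and Mb among its top genes. Free RNA of cardiomyocytes was not tested and is not excluded.

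Cardiomyocyte nuclei had 26 genes past the threshold, 12 higher and 14 lower. The stress-induced cornified envelope gene Sprr1a rose by log2 0.91 ± 0.11 (adjusted p = 0.00775; 90.6 and 75.2 against 42.1 and 44.7 CPM), and the adhesion gene Ncam1 by 0.92 ± 0.09 (adjusted p = 0.00222), while Saa3 fell by 1.88 ± 0.31 (adjusted p = 0.04). Glycolysis (median 0.17, 14 of 15 positive) and oxidative phosphorylation (0.12, 15 of 16 positive) were called upward by camera (adjusted p = 0.000376 and 0.00048; both adjusted p = 0.763 with an estimated correlation), with 0 single genes called by edgeR or DESeq2 in either, 0 adjusted over the list alone, and 4 in each at an unadjusted p under 0.05 in edgeR against 1 in each in DESeq2. Without control replicate 1 or 2, 0 genes were called by edgeR, with 1239 and 1009 at an unadjusted p under 0.05, and without knockout replicate 1 or 2, 106 and 177 were called.

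Fibroblast nuclei had 81 genes past the threshold (28 higher, 53 lower). Depth in this class differed with genotype, at medians of 8284.5 and 10189 UMIs in resHif1aKO against 3654 and 6429 in control, and a shallow cluster within it, led by Gphn, held 274 and 126 against 873 and 476 nuclei. The stress genes Dusp1 (log2 0.58 ± 0.10) and Ddit4 (0.46 ± 0.10), and the membrane repair gene Anxa2 (0.46 ± 0.04, adjusted p = 4.31e-05; 363 and 353 against 263 and 252 CPM), were higher, and the acute-phase gene Saa3 was lower (-2.39 ± 0.15, adjusted p = 3.57e-07; 3.96 and 3.14 against 18.6 and 18.2 CPM). Scgb1a1 fell there too, on 2 against 96 UMIs (51.3-fold lower, 13.8 to 430). Endothelial markers in these nuclei fell by 0.60 (4 of 8 called, 6 adjusted over the list alone; camera adjusted p = 2.25e-12; adjusted p = 0.30 with an estimated correlation). MHC class II genes fell by 0.40 (0 of 7 called by edgeR and 0 by DESeq2, 4 and 2 at an unadjusted p under 0.05, 2 adjusted over the list alone; 0.000317; adjusted p = 0.498 with an estimated correlation). Without knockout replicate 1 or 2, edgeR called 0 genes (873 and 715 at an unadjusted p under 0.05), and without control replicate 1 or 2 it called 17 and 43.

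Vascular endothelial nuclei had 143 genes past the threshold (120 higher, 23 lower), and the 8 highest folds included Sirpb1c (log2 2.12 ± 0.27, adjusted p = 0.000921; 14.5 and 22.3 against 3.82 and 4.40 CPM), Siglecf, Slc37a1, Rasgrp4, Med12l and Adra1a. Siglecf is also among the top genes of a neutrophil-like cluster, and Sirpb1c of a macrophage or monocyte-like cluster. Markers of other cells were called in these nuclei too: 4 of 5 erythroid, 1 of 7 neutrophil and 1 of 9 cardiomyocyte genes by edgeR. With doublets kept, 71 of the 143 genes were called again. Whether RNA or nuclei of other cells account for these rises was not tested. Saa3 fell again (-1.85 ± 0.22, adjusted p = 0.000427). Complement genes of tissue macrophages rose (median 0.50, 2 of 12 called, 10 adjusted over the list alone; camera adjusted p = 2.78e-10; adjusted p = 0.187 with an estimated correlation). Lipid-associated genes rose by 0.22 (0 of 15 called by edgeR and 0 by DESeq2, 9 and 5 at an unadjusted p under 0.05, 6 adjusted over the list alone; 3.78e-06; adjusted p = 0.187 with an estimated correlation). Leaving out knockout replicate 2 gave 74 genes, and leaving out control replicate 1 or 2 gave 235 and 309.

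Pericyte nuclei had 38 genes past the threshold (27 higher, 11 lower). The neutrophil attractant Cxcl1 rose by log2 2.00 ± 0.26 (adjusted p = 0.000152; 47.6 and 37.6 against 11.7 and 9.37 CPM), and the wound matrix gene Tnc (-1.26 ± 0.19, adjusted p = 0.00127; 134 and 172 against 484 and 245 CPM) and the leukocyte adhesion gene Sele (-0.98 ± 0.21, adjusted p = 0.0344) fell. Of 8 endothelial markers in these nuclei, edgeR and DESeq2 called 0, with 4 and 0 at an unadjusted p under 0.05. Whether RNA or nuclei of other cells, such as endothelium, account for changes in this class was not tested. Inflammatory cytokine genes had a median of 1.00 (1 of 5 called, 2 adjusted over the list alone; camera adjusted p = 0.0131; adjusted p = 0.535 with an estimated correlation). Leaving out knockout replicate 1 or 2, or control replicate 1 or 2, gave 72, 74, 122 and 80 pericyte genes. Gphn and Cmss1, which lead an unnamed cluster with a median of 1152 UMIs, were lower in 5 of 5 classes, Gphn from -0.66 to -0.84 and Cmss1 from -0.48 to -0.62 on the log2 scale.

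**Figure D4:**
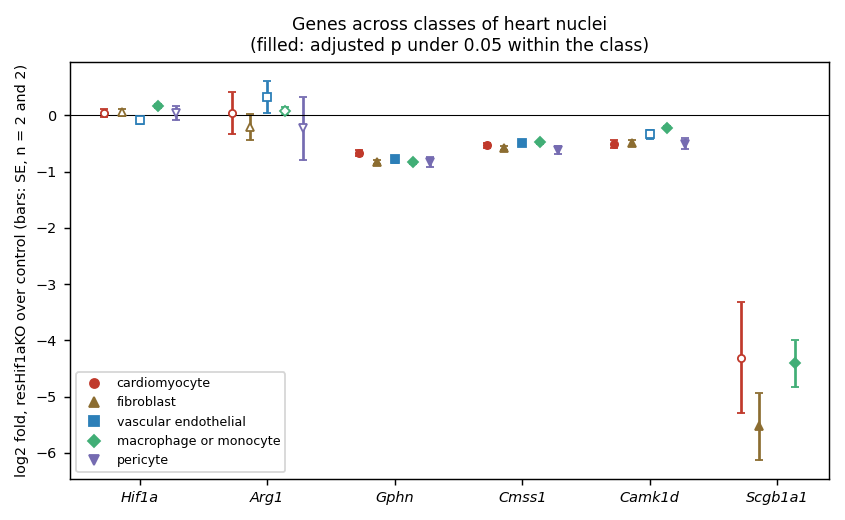
Log2 folds of resHif1aKO over control nuclei with SE bars for 6 genes in up to 5 classes (n = 2 and 2 libraries); filled points have an adjusted p under 0.05 within the class. Gphn is lower in the 5 classes and Scgb1a1, on very few knockout UMIs, has a log2 fold of -5.53 in fibroblast, -4.41 in macrophage or monocyte and -4.31 in cardiomyocyte nuclei, the last not called (adjusted p = 0.165).

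Among 16 classes of nuclei, the epicardial-like share differed: 5.12% and 5.33% in resHif1aKO against 2.45% and 2.54% in control (log2 1.07 ± 0.10, edgeR adjusted p = 0.00792). The epicardial-like share was also called by edgeR at resolutions 0.5 and 1.5 (log2 1.06 and 1.15) and with doublets kept (0.97). It was called too with cardiomyocyte nuclei or unnamed clusters left out of the total (1.08 and 0.90). Without knockout replicate 1 or 2 its log2 fold was 1.09 and 1.04. In the edgeR fit with a replicate block this share was not called (log2 1.07, adjusted p = 0.0593). Without control replicate 1 or 2 the adjusted p was 0.119 and 0.109 at log2 1.04 and 1.09, and 0 classes were called by edgeR (2 and 5 at an unadjusted p under 0.05). Cardiomyocyte-like nuclei were 4.42% and 4.57% against 3.24% and 3.29% (adjusted p = 0.0804), and 6 classes had an unadjusted p under 0.05. Macrophage or monocyte-like nuclei were 25.7% and 26.7% against 23.4% and 26.3% (adjusted p = 0.542), fibroblast-like 16.6% and 16.8% against 19.8% and 16.6% (adjusted p = 0.42), and unnamed clusters 7.14% and 1.09% against 15.9% and 13.5%. An exact permutation test of 2 against 2 libraries cannot reach 0.05. Arg1 UMIs were in 8.30% and 8.67% of resHif1aKO and 6.82% and 7.48% of control nuclei, and in 4.13% and 3.63% against 3.63% and 3.80% after thinning (2441, 1352, 4133 and 3701 left out). After thinning, macrophage or monocyte-like nuclei gave 8.80% and 8.20% against 7.87% and 8.58%, and T or NK-like nuclei 3.50% (1.37 to 7.89) and 4.20% (1.80 to 8.92) against 3.45% (0.964 to 8.74) and 3.05% (0.825 to 7.52), at medians of 4090.5 and 3521 against 3935 and 3710 UMIs. The shares over all nuclei lay inside these T or NK-like intervals.

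**Figure D5:**
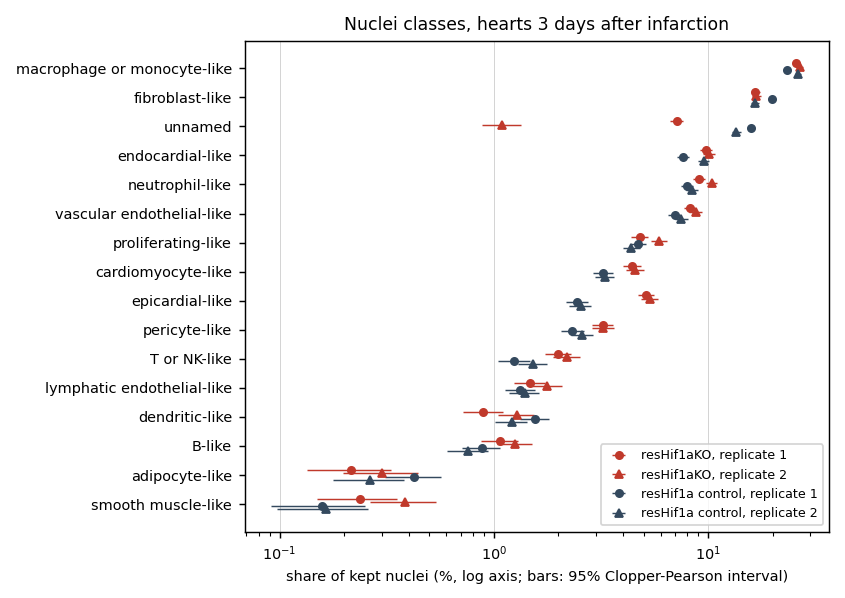
Share of kept nuclei in each class (percent, log axis) in 2 resHif1aKO and 2 control libraries, with 95% Clopper-Pearson intervals as bars. Epicardial-like nuclei are 5.12% and 5.33% in resHif1aKO and 2.45% and 2.54% in control.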

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

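The results here are values that moved in opposite directions between groups under the same contrast, Arg1 levels that ran against the design, genes foreign to the heart, and the count of genes that part the fate label. The tests of explanations below were all chosen after the results had been seen.

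Airway secretory genes were lower in resHif1aKO than in control nuclei, a pattern spread over cell classes. Fewer UMIs per nucleus in the knockout libraries were ruled out, because the lower knockout median was 1.31 times the higher control median. The fall was not confined to macrophage nuclei: Scgb1a1 had a log2 fold of -5.53 ± 0.60 in fibroblast nuclei (2 against 96 UMIs), and its fold in macrophages differed from that by 1.12 ± 0.725. A change made only in macrophages is not excluded by this, because free RNA from any cell would give a similar fold in both classes. Free RNA of airway epithelium stays open. In the control libraries, 8 airway genes listed after they had been seen gave 99.3 UMIs per 1000 epicardial-like nuclei against a median of 76.6 over the 13 named classes with at least 50 nuclei in every library, an even spread (ratio 1.30). The classes left out of that median were not all even: adipocyte-like control nuclei held 2187 per 1000, or 28.5 times the median (161 and 3 UMIs in 46 and 29 nuclei), and unnamed nuclei 1409 per 1000. Airway material was in both groups. A cluster led by Cyp2f2, Scgb3a1 and Sftpc had 18 and 19 nuclei in resHif1aKO and 36 and 62 in control, with 547 and 398 against 1149 and 3017 airway UMIs, and 25 nuclei of an alveolar cluster lay in control replicate 2 alone. No biological explanation beyond the genotype was tested.

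Arg1 was higher, not lower, in the macHif1aKO library. After each cell had been thinned, the ratio of shares of cells with an Arg1 UMI was 2.89 (2.00 to 4.16), which argues against depth, and T or NK-like and neutrophil-like cells held Arg1 at 16.3% (upper bound 20.9%; 63 UMIs, 977 cells) of the level over all cells, which argues against free RNA as the whole source. With cluster sizes fixed at those of the control, the ratio was 1.56 (1.45 to 1.68), and over clusters named monocyte or macrophage alone the log2 ratio was 0.73 against 1.59 over all cells, so the kinds of cells sorted may account for part of the rise and could not be excluded. The named clusters leave out an unnamed cluster of 844 cells with Hilpda and Spp1 among its top genes, so the value of 0.73 does not cover all macrophages. Loss of Hif1a in macrophages, sex and batch stay open, with 1 library per group.

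Arg1 was higher in the library labelled DTR, although the transgene was built to remove cells of the Arg1 lineage. Over cells with at least 2000 UMIs the ratio was 1.61 (1.57 to 1.64). Cells under 2000 UMIs hold too few of the summed UMIs for their removal to move this ratio much. The result was thus fixed in advance, and it shows only that such cells hardly dilute the summed value. With cluster sizes fixed, it was 1.24 (1.21 to 1.27), so composition may explain part of it and cannot be told apart from a change within clusters. Over clusters named monocyte or macrophage alone, the log2 ratio was 0.94 against 0.67 over all cells. This cannot decide on composition, because the mix within those clusters was not held fixed. Monocyte-like cells were 16.3% of DTR and 3.66% of control cells, and resident macrophage-like cells 1.66% and 8.34%. Most cells in this experiment are unnamed, among them a cluster of 980 cells with Arg1 among its top genes. An exchange of both labels could not be tested, since 0 transgene names are in the gene list. Resident macrophage genes, whose medians were above 0 in ZsGr+ cells of all 4 pairs, had a median of -0.71 in the DTR library, which runs the way the labels say but excludes nothing. Ablation that was absent, incomplete or followed by refilling is untested.

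The fate label parted 1721 genes over the 4 pairs. Only 1 of the 8 splits that part all 4 pairs reached this number, the real one, and the highest other gave 0, but 8 splits are too few for a share under 0.05.

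The remaining differences were not tested as such. Between ZsGr+ and ZsGr- cells, Hif1aKO over control transplants gave Arg1 log2 ratios of -0.35 and 0.67. The same contrast gave glycolysis medians of -0.38 and 0.19, and oxidative phosphorylation medians of -0.35 and 0.23. Interferon medians were 0.46 and -0.25, endothelial marker medians -0.78 and 0.49, and erythroid medians 2.69 and -2.57. The endothelial and erythroid moves depended on the cells counted: with other lineages left out the endothelial medians were 0.12 and -0.41, and the erythroid median in ZsGr+ cells was -1.02 with at least 1000 genes per cell and -1.42 in clusters named monocyte or macrophage. Between day 2 and day 30 of MI, ZsGr+ over ZsGr- cells gave Arg1 log2 ratios of 1.53 and -2.05 and hypoxia-inducible medians of 0.36 and -0.36. In control and Hif1aKO transplants, the Hif1a log2 ratio of ZsGr+ over ZsGr- cells was -0.39 and 0.14, and the erythroid median -1.30 and 4.01. Among nuclei, MHC class II medians were -0.40 in fibroblast and 0.36 in endothelial nuclei. Efferocytosis medians were -0.25 in cardiomyocyte, 0.19 in endothelial and -0.056 in macrophage nuclei. Cardiomyocyte marker medians were -0.080 in fibroblast, 0.32 in endothelial, 0.22 in macrophage and 0.17 in pericyte nuclei.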

How the results depend on the processing

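Depth limits these results most in ZsGr+ day 30, with 8794761 UMIs, where 0 counts leave a floor of 0.341 CPM, and in shares of cells with a UMI, since median depths ran from 1889.5 to 17457 UMIs. Below, label means ZsGr+ over ZsGr-, time means day 30 over day 2 of MI, and genotype means Hif1aKO over control transplant. Except where stated, the cause of a change was not tested. The planned and added alternatives left 27 of 60 Arg1 ratios, 16 of 30 Arg1 shares, 12 of 40 monocyte or macrophage shares, 343 of 444 class shares and 1199 of 1386 list medians within their error, and 880 of 1202 fits of named genes on the same side of the threshold, 0 of them reversed.

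Over the ZsGr pairs, edgeR called 1721 genes, 2635 with no filter on low counts, 14 with no block for the pair (1 higher, 13 lower) and 957 with other lineages left out. Leaving out a pair gave 535 to 2328. The 17 lists fell to 0 with an estimated correlation.

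In nuclei, DESeq2 called 52 genes in fibroblast, 70 in endothelial, 76 in macrophage and 10 in pericyte nuclei, against 81, 143, 322 and 38 by edgeR. No filter on low counts gave 0 in cardiomyocyte nuclei (26 as reported; 1205 at an unadjusted p under 0.05, DESeq2 38 with the filter), 0 in fibroblast (1264 unadjusted), 375 in endothelial, 502 in macrophage and 19 in pericyte nuclei. A replicate block, which pairs libraries only by number, gave 304 in cardiomyocyte, 164 in fibroblast and 366 in endothelial nuclei. Across genes, the pairing correlations were 0.080, -0.0018, 0.00059, 0.0037 and 0.016 in the 5 classes, and over genes of at least 50 CPM they were 0.169 in cardiomyocyte, 0.038 in fibroblast, 0.064 in endothelial, -0.086 in macrophage and 0.045 in pericyte nuclei, so a weak pairing in cardiomyocyte nuclei is not excluded. With doublets kept, 11, 169 and 12 genes were called in cardiomyocyte, fibroblast and pericyte nuclei, and with at least 500 genes per nucleus 20 in pericyte nuclei. Leaving out 1 library, with the lone sample of a group assumed to vary like the other group, gave 0 to 177 genes in cardiomyocyte, 0 to 43 in fibroblast, 74 to 309 in endothelial and 72 to 122 in pericyte nuclei. The lists called in cardiomyocyte, fibroblast, endothelial, macrophage and pericyte nuclei (5, 9, 14, 6 and 8) fell to 0 in each with an estimated correlation. Class shares called in nuclei numbered 1, with 0 under a replicate block (4 at an unadjusted p under 0.05), 5 with doublets kept, 6 and 7 at resolutions 0.5 and 1.5, and 0 to 6 without 1 library.

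Arg1 log2 ratios as reported were macHif1aKO 1.59, day 2 label 1.53, day 30 label -2.05, ZsGr+ time -6.91, ZsGr- time -3.33, control HTX label 1.28, Hif1aKO HTX label 0.26, ZsGr+ genotype -0.35, ZsGr- genotype 0.67 and Arg1DTR 0.67. With TMM scaling, the values were 1.80 in macHif1aKO, 1.71 in day 2 label, 1.59 in control HTX label, -0.61 in ZsGr+ genotype, 0.74 in ZsGr- genotype and 0.78 in Arg1DTR. With doublets kept, they became 1.46 in day 2 label, 1.22 in control HTX label and -0.33 in ZsGr+ genotype. With at least 1000 genes per cell, they became 1.47 in day 2 label, 1.24 in control HTX label and 0.62 in ZsGr- genotype. With no mitochondrial filter, they became 1.49 in day 2 label, 1.21 in control HTX label, 0.29 in Hif1aKO HTX label, -0.32 in ZsGr+ genotype and 0.60 in ZsGr- genotype. With only clusters named monocyte or macrophage, they became 0.73 in macHif1aKO, 1.17 in day 2 label, -0.89 in day 30 label, -6.25 in ZsGr+ time, -4.19 in ZsGr- time, 1.02 in control HTX label, -0.27 in Hif1aKO HTX label, -0.73 in ZsGr+ genotype, 0.56 in ZsGr- genotype and 0.94 in Arg1DTR. With other lineages left out, they became 1.35 in macHif1aKO, 1.49 in day 2 label, -3.08 in ZsGr- time, 0.95 in control HTX label, 0.099 in Hif1aKO HTX label and 0.50 in ZsGr- genotype.

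Differences in the share of cells with an Arg1 UMI, in percentage points, were macHif1aKO 10.8, day 2 label 50.03, ZsGr+ time -72.5, ZsGr- time -21.1, control HTX label 38.1, Hif1aKO HTX label 24.5, ZsGr+ genotype -0.470, ZsGr- genotype 13.2 and Arg1DTR 7.46. With at least 1000 genes per cell, the values were 46.0 in day 2 label, -75.8 in ZsGr+ time, -27.9 in ZsGr- time, 47.3 in control HTX label, -8.40 in ZsGr+ genotype and 3.15 in Arg1DTR. With thinning to 2000 UMIs, they became 4.32 in macHif1aKO, 31.5 in day 2 label, -49.0 in ZsGr+ time, -16.8 in ZsGr- time, 26.6 in control HTX label, 9.95 in Hif1aKO HTX label, -7.17 in ZsGr+ genotype and 9.53 in ZsGr- genotype.

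Differences in the share of cells in clusters named monocyte or macrophage were, in percentage points, macHif1aKO -4.24, day 2 label -12.6, day 30 label 21.7, ZsGr+ time 53.4, ZsGr- time 19.0, control HTX label 12.6, Hif1aKO HTX label -4.92, ZsGr+ genotype 8.29, ZsGr- genotype 25.8 and Arg1DTR 5.42. With doublets kept, the values were -0.810 in macHif1aKO, -16.3 in day 2 label, 13.3 in day 30 label, 47.4 in ZsGr+ time, -8.09 in control HTX label, -19.5 in Hif1aKO HTX label, 13.4 in ZsGr+ genotype and 1.99 in Arg1DTR. With at least 1000 genes per cell, they became -26.4 in day 2 label, 8.998 in ZsGr- time, 3.88 in control HTX label, -24.7 in Hif1aKO HTX label, -19.2 in ZsGr+ genotype, 9.36 in ZsGr- genotype and -5.03 in Arg1DTR. With resolution 0.5, they became -6.06 in day 2 label, 45.1 in ZsGr+ time, 18.2 in control HTX label, 15.4 in ZsGr+ genotype, 37.1 in ZsGr- genotype and 14.99 in Arg1DTR. With resolution 1.5, they became 13.3 in day 30 label, 46.8 in ZsGr+ time, 2.56 in control HTX label, -20.6 in Hif1aKO HTX label, -0.791 in ZsGr+ genotype, 22.4 in ZsGr- genotype and -4.69 in Arg1DTR.

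With at least 1000 genes per cell, the erythroid median turned from 2.69 to -1.02 in ZsGr+ genotype. Counting only clusters named monocyte or macrophage turned more list medians, but it also left out unnamed clusters with Arg1, Hilpda or Spp1 among their top genes. In macHif1aKO they were glycolysis 0.26 to -0.033, matrix and fibrosis -1.61 to 0.19, angiogenesis -0.99 to 0.0014 and fibroblast markers -1.45 to 0.24. In day 2 label it was hypoxia-inducible targets 0.36 to -0.16. In day 30 label they were hypoxia-inducible targets -0.36 to 0.0047 and cell cycle 0.44 to -0.092. In ZsGr+ time they were interferon response 1.03 to -0.24, inflammatory cytokines -1.10 to 0.76 and matrix and fibrosis 2.99 to -2.25. In ZsGr- time they were interferon response 0.43 to -0.075, cell cycle -0.72 to 0.013 and matrix and fibrosis 2.25 to -1.04. In control HTX label they were complement and tissue macrophage 0.40 to -0.025, matrix and fibrosis -0.79 to 0.12, fibroblast markers -0.92 to 0.24 and erythroid markers -1.30 to 0.36. In Hif1aKO HTX label it was fibroblast markers -1.09 to 0.35. In ZsGr+ genotype they were matrix and fibrosis 0.45 to -0.15 and erythroid markers 2.69 to -1.42. In ZsGr- genotype it was inflammatory cytokines -0.43 to 0.14. Leaving out clusters of other lineages, chosen after seeing the data, turned these. In macHif1aKO they were T and NK cell markers -0.58 to 0.62 and fibroblast markers -1.45 to 0.031. In ZsGr+ time they were matrix and fibrosis 2.99 to -0.96 and endothelial markers 3.21 to -0.71. In ZsGr- time it was matrix and fibrosis 2.25 to -0.50. In Hif1aKO HTX label they were B cell markers -0.78 to 0.26 and fibroblast markers -1.09 to 0.016. In ZsGr+ genotype they were matrix and fibrosis 0.45 to -0.17, angiogenesis -0.085 to 0.0076 and endothelial markers -0.78 to 0.12. In ZsGr- genotype they were matrix and fibrosis 0.67 to -1.07, fibroblast markers 0.48 to -1.66, endothelial markers 0.49 to -0.41 and cardiomyocyte markers 0.37 to -0.58. In Arg1DTR it was B cell markers 1.18 to -0.63. Class shares that changed direction, in percentage points, were inflammatory-like in ZsGr- time 2.62 to -1.80 (resolution 0.5), MHC-II macrophage-like in control HTX label 7.04 to -1.71 (resolution 1.5), MHC-II macrophage-like in Hif1aKO HTX label 13.4 to -2.95 (resolution 1.5), MHC-II macrophage-like in ZsGr+ genotype 11.3 to -7.00 (at least 1000 genes per cell). Others were cardiomyocyte-like in ZsGr+ genotype 1.94 to -0.265 (at least 1000 genes per cell), lipid-associated macrophage-like in ZsGr+ genotype -3.42 to 3.17 (resolution 0.5) and MHC-II macrophage-like in ZsGr- genotype 4.97 to -0.137 (at least 1000 genes per cell).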

Other observations

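Clusters within the macrophage or monocyte nuclei were tested only after the classes had been seen. A cluster led by Cd163, F13a1 and Vsig4 held 8.60% and 8.82% of these nuclei in resHif1aKO and 6.87% and 7.17% in control (log2 0.31 ± 0.086, edgeR adjusted p = 0.0175). A cluster led by Ccr2 and Adgre4 held 22.6% and 22.2% against 20.01% and 18.2% (0.23 ± 0.071, adjusted p = 0.0212), and a shallow cluster with a median of 1075.5 UMIs, led by Nppa and Gphn, held 25.7% and 22.0% against 28.3% and 30.9% (-0.31 ± 0.084, adjusted p = 0.0175).

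Saa3, an acute-phase gene, was 70.7-fold higher in ZsGr+ and 3.04-fold higher in ZsGr- cells of Hif1aKO transplants, and lower in resHif1aKO nuclei of cardiomyocytes, fibroblasts and endothelium (log2 -1.88, -2.39 and -1.85). In the transplant libraries, Saa3 was among the 10 leading genes of unnamed clusters of 198 and 437 cells. The folds over all kept cells there do not separate cluster sizes from expression per cell. In nuclei, Saa3 was also among the 10 leading genes of an unnamed cluster with a median of 1152 UMIs, and unnamed nuclei were 7.14% and 1.09% in resHif1aKO against 15.9% and 13.5% in control. No explanation was tested.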
